A study of Homo sapiens with 18 samples.

How the data were processed

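RNA from 18 samples of the human multiple myeloma line JJN3 was measured by QuantSeq 3′ mRNA sequencing: DMSO, B32B3 and VPR8 after 6 h and 24 h, 3 samples per group. Sample titles spell the first compound B2B3 and the treatment label spells it B32B3; the latter is used here. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, trimmed with cutadapt 1.14, aligned with HISAT2 2.0.4 and counted per gene with featureCounts of Subread 2.0.0, and edgeR 3.38.1 and limma 3.52.1 were used afterwards. The deposited values are raw gene counts, 1 column per sample, and 0 columns were left unmapped. The notes name the human build hg19, while 58039 of the 58302 gene identifiers belong to GENCODE release 29, so the annotation looks newer than the stated build and no coordinates are given. The annotation release, the strand setting and the treatment of reads that fit several genes are not stated in the sources used here. Symbols were taken for 57532 identifiers, and 0.176% of counts lay on identifiers without one.

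All later steps were computed here from the deposited counts, with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and bedtools 2.31.1. Totals were 6278785 to 8095567 counts per sample. Levels are CPM with TMM-scaled library sizes (factors 0.955 to 1.036), and a level from 3 counts is 0.371 CPM in the deepest and 0.478 CPM in the shallowest sample, counting error only. Genes were kept by edgeR's filterByExpr on the groups (minimum count 10, minimum total 15), leaving 13724 genes with 99.77% of the counts. Within groups the counts varied more than counting error, with a chi-squared statistic per degree of freedom of 1.258 to 3.395. It was 1.393 to 3.395 at 6 h and 1.258 to 2.035 at 24 h, while the main fit shared 1 spread per gene over both times. Counts of called genes may therefore be too high at 6 h and too low at 24 h. The common dispersion was 0.00192, a coefficient of variation of 4.39% between samples of a group.

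Comparisons were each compound against DMSO at the same time, VPR8 against B32B3 at each time, the effect of each compound at 24 h minus that at 6 h, and DMSO at 24 h against 6 h. Each used edgeR's robust quasi-likelihood F test in a fit of all 18 samples with 1 mean per group (12 residual degrees of freedom), with p-values adjusted by Benjamini-Hochberg within a comparison. A gene is called at an adjusted p below 0.05. Intervals are 95%. The 27 gene lists were written from textbook knowledge (777 entries, of which 775 were found) and those with at least 3 tested members were tested by limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 27 lists, and again with a correlation estimated from the data. Member counts are given over all genes and adjusted over the list alone. The design, the lists, 12 single genes, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 6 largest increases and 6 largest decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap of the samples' values between groups, up to 4 called members of each list with the smallest p, the 12 single genes and every tubulin. Genes named in 1 comparison were followed through the others.

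Scripts were tested on simulated data of 13724 genes with 50 planted changes per size. For B32B3 at 24 h 28% of 1.25-fold, 70% of 1.5-fold, 82% of 2-fold and 98% of 4-fold changes were recovered, with 8 false calls among 162. For VPR8 at 6 h these were 38%, 58%, 66% and 98%, with 8 false calls among 138. For VPR8 at 24 h they were 36%, 64%, 76% and 98%, with 14 false calls among 151, and for B32B3 at 6 h there were 8 false calls among 145. All but the first of these shares of false calls lie above the 5% aimed at, that of VPR8 at 24 h the most.

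Alternatives fixed in advance were RLE scaling, DESeq2, limma-voom, no and a stricter filter on low counts (10 counts in 9 samples), a log2 change of at least 1, the samples of 1 time point alone, the replicate number as a block, leaving out each sample in turn, and for lists an estimated correlation and limma's fry. Chosen after the data were seen were the share of long intergenic noncoding RNA per sample as a covariate, and a fit without genes whose exons overlap those of a tested gene with more counts. Exons of 5773 tested genes overlap another tested gene, and reads of such pairs and of near-identical paralogues such as tubulins, histones and ribosomal protein genes cannot be assigned with certainty. Correlation between the compounds was compared with unchanged groups simulated against the same controls. Raw reads were not analysed here, and some genes that the naming rule selects are not reported here.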

Results

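JJN3, a human multiple myeloma (malignant plasma cell) line, was treated with B32B3, a small-molecule inhibitor of the kinase activity of VPRBP (gene DCAF1, the substrate receptor of a CRL4 ubiquitin ligase), with a compound code-named VPR8, or with the solvent DMSO. Polyadenylated RNA was measured after 6 h and 24 h by QuantSeq, which reads mainly the 3′ end of each transcript. The series concerns analogues of VPRBP kinase inhibitors that destabilise microtubules and act against myeloma cells, so each compound was compared with DMSO at each time. The compounds were compared with each other, and each compound's effect was compared between times. There were 6 groups of 3 libraries each, 18 libraries in all. Total counts ranged from 6278785 to 8095567 per library. The group means (± SD, n = 3) were 7.24 ± 0.205 M for DMSO, 7.28 ± 0.761 M for B32B3 and 6.79 ± 0.376 M for VPR8 at 6 h. At 24 h they were 7.0 ± 0.269 M for DMSO, 7.48 ± 0.275 M for B32B3 and 6.95 ± 0.588 M for VPR8. A gene with 3 counts, the limit that a count of 0 allows, stood at 0.371 to 0.478 CPM, counting error only. The labels give no doses, so it cannot be judged whether the compounds were used at matched doses. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

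The largest difference lay between the 6 h and the 24 h libraries, whose names also fall in separate blocks. The first principal component held 49.6% of the variance and separated 6 h from 24 h. The second held 6.3% and, at 24 h, placed DMSO at 12.16 to 13.06, VPR8 at 0.42 to 4.56 and B32B3 at -14.21 to -10.77. At 6 h, 3 treated libraries carried more long intergenic noncoding RNA (lincRNA) than the rest. Its share of counts was 0.958% and 0.962% in B32B3 replicates 1 and 3 and 0.945% in VPR8 replicate 3, against 0.632% in B32B3 replicate 2, 0.685% and 0.684% in the other VPR8 libraries, and 0.57% to 0.676% in DMSO. The nuclear transcript MALAT1, itself a lincRNA, made up a large part of this share. It held 0.532%, 0.54% and 0.531% of counts in those 3 libraries against 0.226% to 0.315% in DMSO at 6 h, so it is no separate observation. At 24 h the lincRNA share was 1.093% to 1.142% in DMSO, 1.186% to 1.367% in B32B3 and 1.145% to 1.27% in VPR8.

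After 6 h of B32B3, genes of cholesterol synthesis rose together. INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum, rose from 1014 ± 32.7 to 2818 ± 44.2 CPM (mean ± SD, n = 3 per group), a log2 change of 1.48 ± 0.04 (± SE). MSMO1, a sterol demethylase, rose from 61.1 ± 4.63 to 148 ± 2.78 CPM (1.28 ± 0.06), and SQLE, the squalene epoxidase, rose from 214 ± 8.26 to 349 ± 17.6 CPM (0.71 ± 0.05). HMGCS1, an early enzyme of the pathway, rose by 1.15 ± 0.04. In all, 17 of 25 tested members of the cholesterol list rose over all genes, 18 adjusted over the list alone, and none fell (median log2 0.39; camera adjusted p = 5.73e-28, and 0.000269 with an estimated correlation). HMGCS1 shares exon sequence with another tested gene on the opposite strand (ENSG00000261604), so its value is uncertain.

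Stress-related groups also rose at 6 h of B32B3. Among ER chaperones and unfolded protein response genes, 9 of 25 rose over all genes and 10 adjusted over the list alone, led by HERPUD1, a factor of ER-associated degradation (0.94 ± 0.06), HSPA5, the ER chaperone BiP (776 ± 15 to 984 ± 33 CPM; 0.34 ± 0.04), and SEL1L (0.34 ± 0.06; list median 0.17, camera adjusted p = 4.13e-07, and 0.0197 with an estimated correlation). In the ATF4-linked integrated stress response list, 6 of 31 rose over all genes and 9 adjusted over the list alone, including PPP1R15A, which directs dephosphorylation of eIF2α (0.70 ± 0.10), and ATF4 itself (0.28 ± 0.04; list adjusted p = 2.58e-05 by camera, and 0.0158 with an estimated correlation). Of 14 BCL2 family genes, 3 rose over all genes and 6 adjusted over the list alone, among them the anti-apoptotic BCL2 (135 ± 7.17 to 195 ± 1.46 CPM; 0.53 ± 0.05) and the pro-apoptotic BBC3 (0.59 ± 0.07; list adjusted p = 2.52e-05 by camera, and 0.00394 with an estimated correlation). HMOX1, the heme oxygenase, rose from 50.5 ± 4.15 to 103 ± 3.3 CPM (1.02 ± 0.07), and SQSTM1, the autophagy receptor p62, rose by 0.78 ± 0.04. SQSTM1 overlaps MRNIP on the opposite strand. They belong to the NRF2 target list, of which 4 of 18 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00503). With an estimated correlation that list did not pass (adjusted p = 0.185).

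Mitotic and growth genes moved in opposite directions at 6 h of B32B3. Of 45 G2/M genes, 8 rose over all genes; adjusted over the list alone 16 rose and 1 fell (median 0.13; camera adjusted p = 1.15e-07, and 0.000269 with an estimated correlation). They included the spindle motor gene CENPE (373 ± 27.8 to 446 ± 19.5 CPM; 0.26 ± 0.04) and CKAP2, a spindle protein (0.33 ± 0.05). Of 30 ribosome biogenesis and MYC target genes, 12 fell over all genes and 20 adjusted over the list alone, among them NOP58, a small nucleolar RNP protein (-0.23 ± 0.04), and ODC1, the ornithine decarboxylase (-0.30 ± 0.05; list median -0.13, camera adjusted p = 3.03e-10, and 0.0178 with an estimated correlation). MYC itself was 186 ± 16 CPM in DMSO and 171 ± 14.3 under B32B3 and did not pass the test. The plasma cell factor IRF4 fell from 217 ± 5.76 to 182 ± 6.35 CPM (-0.26 ± 0.05), while PIM2, a kinase highly expressed in myeloma, rose by 0.37 ± 0.04. Of 20 plasma cell identity genes, 1 rose and 1 fell over all genes, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.947). Among other single genes, the cannabinoid receptor gene CNR1 rose from 4.31 ± 0.816 to 10.8 ± 0.985 CPM (1.32 ± 0.18). CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell from 14.5 ± 1.38 to 7.03 ± 0.518 CPM (-1.04 ± 0.15), and the phosphatase gene PTP4A3 fell by 0.66 on the log2 scale.

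In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 662 of 13724 genes were called for B32B3 at 6 h, 368 higher and 294 lower, with 28 at least doubled and 6 at least halved. The share higher was 55.6%. The count was 399 (59.6% higher) without DMSO replicate 2, 433 (64%) without DMSO replicate 3, 353 (63.5%) without B32B3 replicate 1 and 363 (68.3%) without B32B3 replicate 3. It was 373 (67.6%) with the 6 h libraries fitted alone, and 279 (69.9%) with each library's lincRNA share as a covariate, which was chosen after the data were seen. Several list calls at 6 h were not kept with an estimated correlation. Of 79 ribosomal protein genes, 6 fell over all genes and 13 adjusted over the list alone (adjusted p = 3e-09 by camera, and 0.365 with an estimated correlation). Of 67 nuclear oxidative phosphorylation genes, 4 fell over all genes and 10 adjusted over the list alone (adjusted p = 2.1e-07, and 0.29 with an estimated correlation). Of 33 proteasome genes, 1 fell over all genes and 0 adjusted over the list alone (adjusted p = 0.00147, and 0.319 with an estimated correlation). Among 23 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 0 passed over all genes or adjusted over the list alone (median 0.23, camera adjusted p = 0.00503, and 0.185 with an estimated correlation). The histone call was lost without B32B3 replicate 2 (adjusted p = 0.0749) or DMSO replicate 3 (adjusted p = 0.281). Of 19 immediate early genes, 4 rose and 2 fell over all genes, and 7 rose and 3 fell adjusted over the list alone, with JUN at 0.51 ± 0.06 and JUND at 0.50 ± 0.06 (adjusted p = 0.0466, and 0.185 with an estimated correlation). That call was lost without DMSO replicate 1 (0.216), DMSO replicate 3 (0.0516), B32B3 replicate 2 (0.0573) or B32B3 replicate 3 (0.118), and with the replicate number as a block (0.0818), as adjusted p-values. The G1/S and DNA replication list, with 0 of 41 called over all genes and 0 adjusted over the list alone, had a median of -0.08 (adjusted p = 0.00513, and 0.039 with an estimated correlation) and was not called with the lincRNA share as a covariate (adjusted p = 0.144). With that covariate the immediate early (adjusted p = 0.0515), oxidative phosphorylation (0.943), ribosomal protein (0.703) and proteasome (0.943) lists did not pass either, the last 2 on the other side of 0.

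**Figure D1:**
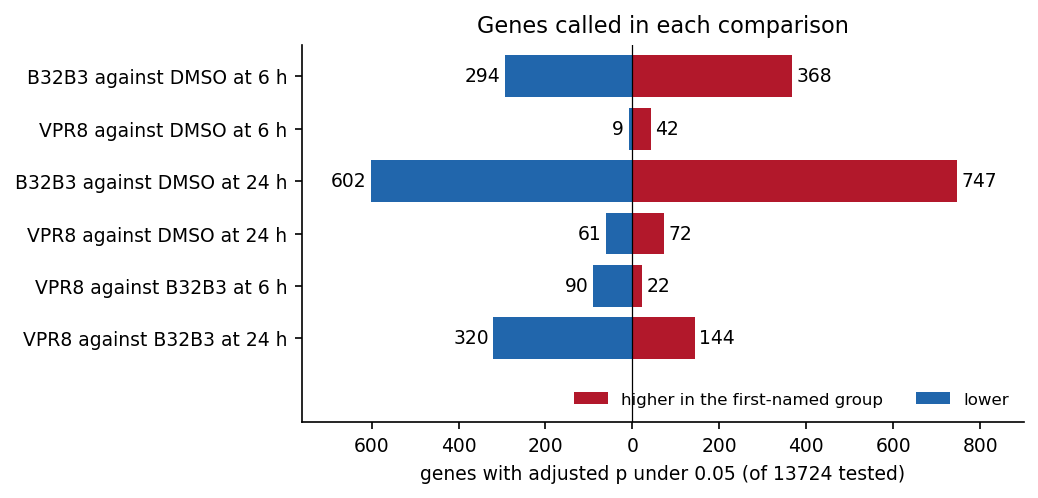
Number of genes called higher and lower in each comparison by edgeR's quasi-likelihood test among 13724 genes, with 3 libraries per group. B32B3 had 662 and 1349 called genes at 6 h and 24 h, and VPR8 had 51 and 133.

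VPR8 after 6 h changed fewer genes than B32B3, sterol genes among them. INSIG1 rose from 1014 ± 32.7 to 1623 ± 65.5 CPM (log2 0.68 ± 0.04), HMGCS1 by 0.57 ± 0.04, MSMO1 by 0.45 ± 0.07 and SQLE by 0.29 ± 0.05. In the cholesterol list 7 of 25 rose over all genes, and adjusted over the list alone 10 rose and 1 fell (median 0.15; camera adjusted p = 3.88e-10, and 0.0252 with an estimated correlation). Of 45 G2/M genes, 4 rose over all genes; adjusted over the list alone 12 rose and 1 fell (median 0.12; camera adjusted p = 2.94e-10, and 9.71e-05 with an estimated correlation). CENPE, the spindle motor, went from 373 ± 27.8 to 448 ± 9.32 CPM (0.26 ± 0.04). TBX3, a developmental transcription factor, rose from 28.6 ± 1.22 to 43.0 ± 2.71 CPM (0.59 ± 0.09), and BCL2 rose by 0.28 ± 0.05. SLIRP, a mitochondrial RNA-binding protein whose gene overlaps SNW1, fell from 412 ± 11 to 353 ± 8.42 CPM (-0.22 ± 0.04).

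edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 51 genes for VPR8 at 6 h, 42 higher and 9 lower (82.4% higher), 7 of them at least doubled. This split depended on the tool: with RLE scaling 56 genes were called and 71.4% were higher, and DESeq2 called 125 genes, of which 25.6% were higher. With the replicate number as a block 135 were called, 56.3% of them higher. limma-voom called 33 genes, and the 6 h libraries alone gave 21. Single left-out libraries gave 117 (without DMSO replicate 1, with 41.9% higher), 30 (DMSO replicate 2), 28 (DMSO replicate 3) and 26 (VPR8 replicate 3, one of the libraries with a high lincRNA share). Other lists lay lower but had few called members. Of 79 ribosomal protein genes 0 fell over all genes and 18 adjusted over the list alone (median -0.09; camera adjusted p = 5.63e-12, and 0.458 with an estimated correlation). Of 67 oxidative phosphorylation genes 0 fell over all genes and 12 adjusted over the list alone (adjusted p = 9.97e-10, and 0.35 with an estimated correlation). Ribosome biogenesis genes had 0 of 30 called over all genes and 4 lower adjusted over the list alone (adjusted p = 5.34e-05, and 0.147 with an estimated correlation). The proteasome list had 0 of 33 called over all genes and 0 adjusted over the list alone (adjusted p = 8.46e-05, and 0.35 with an estimated correlation). The same held for the G1/S list, with 0 of 41 over all genes and 0 adjusted over the list alone (adjusted p = 0.00285, and 0.0535 with an estimated correlation). With the lincRNA share as a covariate 4 of these lists did not pass, with adjusted p-values of 0.131 for ribosomal proteins, 0.0816 for oxidative phosphorylation, 0.287 for the proteasome and 0.0809 for G1/S. Of 14 BCL2 family genes, 1 rose over all genes and 2 adjusted over the list alone (adjusted p = 0.04, and 0.147 with an estimated correlation). The BCL2 family call was lost without DMSO replicate 3 (adjusted p = 0.292), VPR8 replicate 1 (adjusted p = 0.0506) or VPR8 replicate 2 (adjusted p = 0.121), and with the replicate number as a block (adjusted p = 0.0792).

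By 24 h of B32B3 the sterol response covered nearly the whole list. HMGCS1, the cytosolic HMG-CoA synthase, rose from 256 ± 2.53 to 836 ± 22.4 CPM (log2 1.71 ± 0.04), INSIG1 from 1614 ± 25.7 to 3381 ± 91.8 CPM (1.07 ± 0.04), and SQLE by 0.88 ± 0.05. Of 25 members, 22 rose over all genes and 23 adjusted over the list alone (median 0.74; camera adjusted p = 1.71e-37, and 5.98e-05 with an estimated correlation). Larger single changes were seen in the chemokine gene CCL3 (4.12 ± 0.46 to 50.3 ± 4.9 CPM; 3.6 ± 0.13), in SPSB1, a SOCS-box adaptor (2.68 ± 0.32), in SQSTM1 (387 ± 4.76 to 1479 ± 14 CPM; 1.93 ± 0.04) and in HMOX1 (6.75 ± 0.492 to 24.1 ± 3.07 CPM; 1.83 ± 0.13). CCL3 and SQSTM1 overlap CCL3-AS1 and MRNIP on the opposite strand, whose changes were 3.59 and 1.87, and the reads of each pair cannot be told apart. Of 18 NRF2 targets, 9 rose over all genes; adjusted over the list alone 11 rose and 1 fell, with the ferritin light chain gene FTL up from 421 ± 13 to 640 ± 5.45 CPM (0.60 ± 0.04; list adjusted p = 3.43e-10 by camera, and 0.00573 with an estimated correlation).

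Immediate early, NF-κB and p53 target lists were also higher at 24 h of B32B3. Of 19 immediate early genes, 9 rose over all genes and 9 adjusted over the list alone, including EGR1 (2.58 ± 0.549 to 7.67 ± 1.26 CPM; 1.56 ± 0.21), JUND (0.54 ± 0.06) and KLF6 (0.57 ± 0.07; list median 0.36, camera adjusted p = 3.7e-08, and 0.00204 with an estimated correlation). Of 17 NF-κB targets, 4 rose over all genes; adjusted over the list alone 7 rose and 1 fell. These 4 were CCL3, CCL4 (2.25 ± 0.33), the adhesion molecule ICAM1 (1.05 ± 0.19) and the feedback inhibitor TNFAIP3 (0.47 ± 0.07). The list had an adjusted p of 0.00201 by camera, and 0.03 with an estimated correlation. ICAM1 and TNFAIP3 overlap ICAM4-AS1 and WAKMAR2. Of 22 p53 targets, 5 rose over all genes and 5 adjusted over the list alone, such as TP53INP1 (0.77 ± 0.12) and BTG2 (0.73 ± 0.09; list adjusted p = 0.00279 by camera, and 0.027 with an estimated correlation). ER chaperone and unfolded protein response genes had 8 of 25 higher over all genes and 8 adjusted over the list alone, with HERPUD1 at 0.84 ± 0.07 (camera adjusted p = 2.35e-06, and 0.024 with an estimated correlation). In the BCL2 family 4 of 14 rose and 1 fell over all genes, and 7 rose and 1 fell adjusted over the list alone, with BCL2 at 0.24 ± 0.05 (camera adjusted p = 0.00151, and 0.012 with an estimated correlation). The kinase gene PIM2 rose by 0.44 ± 0.04 and the coactivator gene POU2AF1 by 0.29 ± 0.05, whereas MZB1, a plasma cell ER chaperone, fell from 64.0 ± 3.6 to 49.9 ± 3.04 CPM (-0.36 ± 0.07). In the plasma cell identity list 5 of 20 rose and 1 fell over all genes, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.19).

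Cell cycle genes lay lower at 24 h of B32B3. Of 45 G2/M genes, 18 fell over all genes and 30 adjusted over the list alone, such as UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex (90.5 ± 6.26 to 69.2 ± 3.39 CPM; -0.39 ± 0.06), NUSAP1, a spindle protein (-0.26 ± 0.05), and topoisomerase gene TOP2A (1234 ± 16.7 to 1073 ± 8.89 CPM; -0.20 ± 0.04). The list median was -0.18 (camera adjusted p = 4.91e-13, and 2.67e-05 with an estimated correlation). Of 41 G1/S genes, 11 fell over all genes and 15 adjusted over the list alone, such as the helicase subunit gene MCM3 (-0.23 ± 0.04) and the licensing factor gene CDT1 (-0.35 ± 0.07; list median -0.14, camera adjusted p = 4.55e-06, and 0.00253 with an estimated correlation). In the integrated stress response list 4 of 31 rose and 10 fell over all genes, and 5 rose and 10 fell adjusted over the list alone, with PPP1R15A up by 1.25 ± 0.13 and the serine synthesis enzyme genes PSAT1 (-0.48 ± 0.07) and PHGDH (-0.38 ± 0.07) down. The list's camera adjusted p was 0.0174, and 0.111 with an estimated correlation. It was 0.05 without B32B3 replicate 3 and 0.0777 with the lincRNA share as a covariate. Single genes that fell included the interleukin 6 receptor gene IL6R (83.4 ± 5.61 to 43.9 ± 1.7 CPM; -0.93 ± 0.07) and the Wnt agonist gene RSPO2 (-0.93 ± 0.20).

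For B32B3 at 24 h edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1349 genes, 747 higher and 602 lower, with 64 at least doubled and 18 at least halved. The number lower was 396 without DMSO replicate 1, 386 without DMSO replicate 3 and 387 without B32B3 replicate 3. Of 67 oxidative phosphorylation genes 7 fell over all genes and 7 adjusted over the list alone (adjusted p = 0.00155 by camera, and 0.624 with an estimated correlation). With the lincRNA share as a covariate the camera adjusted p of that list was 0.358. Of 33 proteasome genes 5 rose over all genes and 5 adjusted over the list alone (adjusted p = 0.00751, and 0.54 with an estimated correlation).

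**Figure D2:**
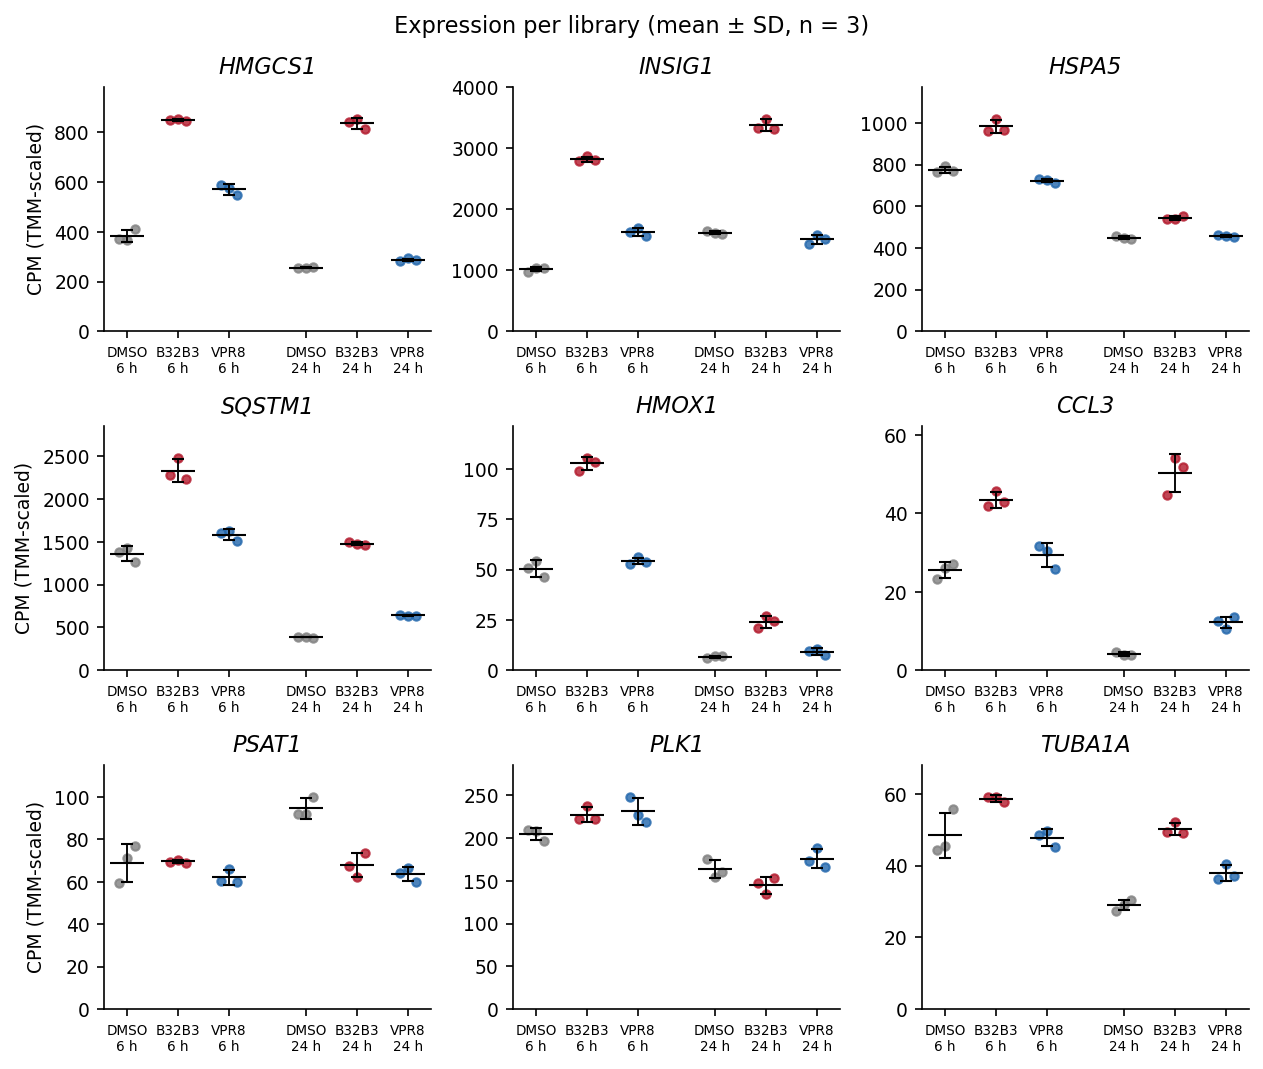
CPM of INSIG1, HMGCS1, SQSTM1, CCL3 and other named genes in each library (points), with group means ± SD of 3 libraries. HMGCS1 at 24 h was 256 ± 2.53 in DMSO, 836 ± 22.4 under B32B3 and 287 ± 5.64 under VPR8.

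After 24 h of VPR8 the clearest group was the integrated stress response list, which lay below DMSO of the same time. Of its 31 genes, 13 fell over all genes; adjusted over the list alone 20 fell and 1 rose (median -0.26; camera adjusted p = 9.04e-20, and 8.68e-05 with an estimated correlation). The members included the glutathione-degrading enzyme gene CHAC1 (38.2 ± 3.47 to 23.2 ± 1.54 CPM; -0.72 ± 0.10), PSAT1 (94.6 ± 4.83 to 63.6 ± 3.31 CPM; -0.57 ± 0.07), PHGDH (87.8 ± 2.99 to 61.0 ± 2.43 CPM; -0.52 ± 0.07), DDIT4 (-0.59 ± 0.08) and ATF4 itself (452 ± 14.6 to 387 ± 4.37 CPM; -0.23 ± 0.04). The argininosuccinate synthase gene ASS1 fell by 0.59 on the log2 scale. CCL3 rose from 4.12 ± 0.46 to 12.2 ± 1.47 CPM (1.56 ± 0.17), SQSTM1 from 387 ± 4.76 to 640 ± 9.22 CPM (0.72 ± 0.04) and FTL by 0.25 ± 0.04. DDIT4, CCL3 and SQSTM1 overlap DDIT4-AS1, CCL3-AS1 and MRNIP on the opposite strand. The small nucleolar RNA genes SNORD13 and SNORD87 rose by 1.26 ± 0.23 and 1.15 ± 0.19. SNORD87 lies within the host gene SNHG6 and SNORD13 overlaps TTI2, so their reads are uncertain. At 6 h CHAC1 was 13.0 to 14.0 CPM in DMSO and 10.4 to 13.6 CPM under VPR8. ATF4 was then 323.2 to 347.5 CPM in DMSO and 332.1 to 351.1 CPM under VPR8. CHAC1 and ATF4 thus rose with time under VPR8, though less than in DMSO. PHGDH was 68.8 to 81.4 CPM under VPR8 at 6 h and was lower there at 24 h.

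The cholesterol list, called at 6 h, had 0 of 25 members called for VPR8 at 24 h over all genes and 2 higher adjusted over the list alone (median 0.04; camera adjusted p = 0.205). INSIG1 was 1614 ± 25.7 CPM in DMSO and 1505 ± 72.9 under VPR8, a log2 change of -0.10 with a 95% interval of -0.18 to -0.02 that did not pass after adjustment. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 133 genes were called, 72 higher and 61 lower, with 10 at least doubled and 1 at least halved. The count was 70, 69 and 76 without DMSO replicates 1, 2 and 3, 81 without VPR8 replicate 1 and 86 without VPR8 replicate 3. Without VPR8 replicate 2 it was 130, with 42.3% higher against 54.1% with all libraries. It was 254 with the 24 h libraries fitted alone, and 219 with the lincRNA share as a covariate. Of 41 G1/S genes 0 were called over all genes and 3 fell adjusted over the list alone (camera adjusted p = 0.00465, and 0.0514 with an estimated correlation). Of 19 immediate early genes 2 rose over all genes and 4 adjusted over the list alone (adjusted p = 0.0107, and 0.124 with an estimated correlation). Without DMSO replicate 3 the number of called lists went from 3 to 1, since neither of these passed (adjusted p = 0.0541 and 0.103). Without VPR8 replicate 2 the immediate early list did not pass (adjusted p = 0.0803).

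**Figure D3:**
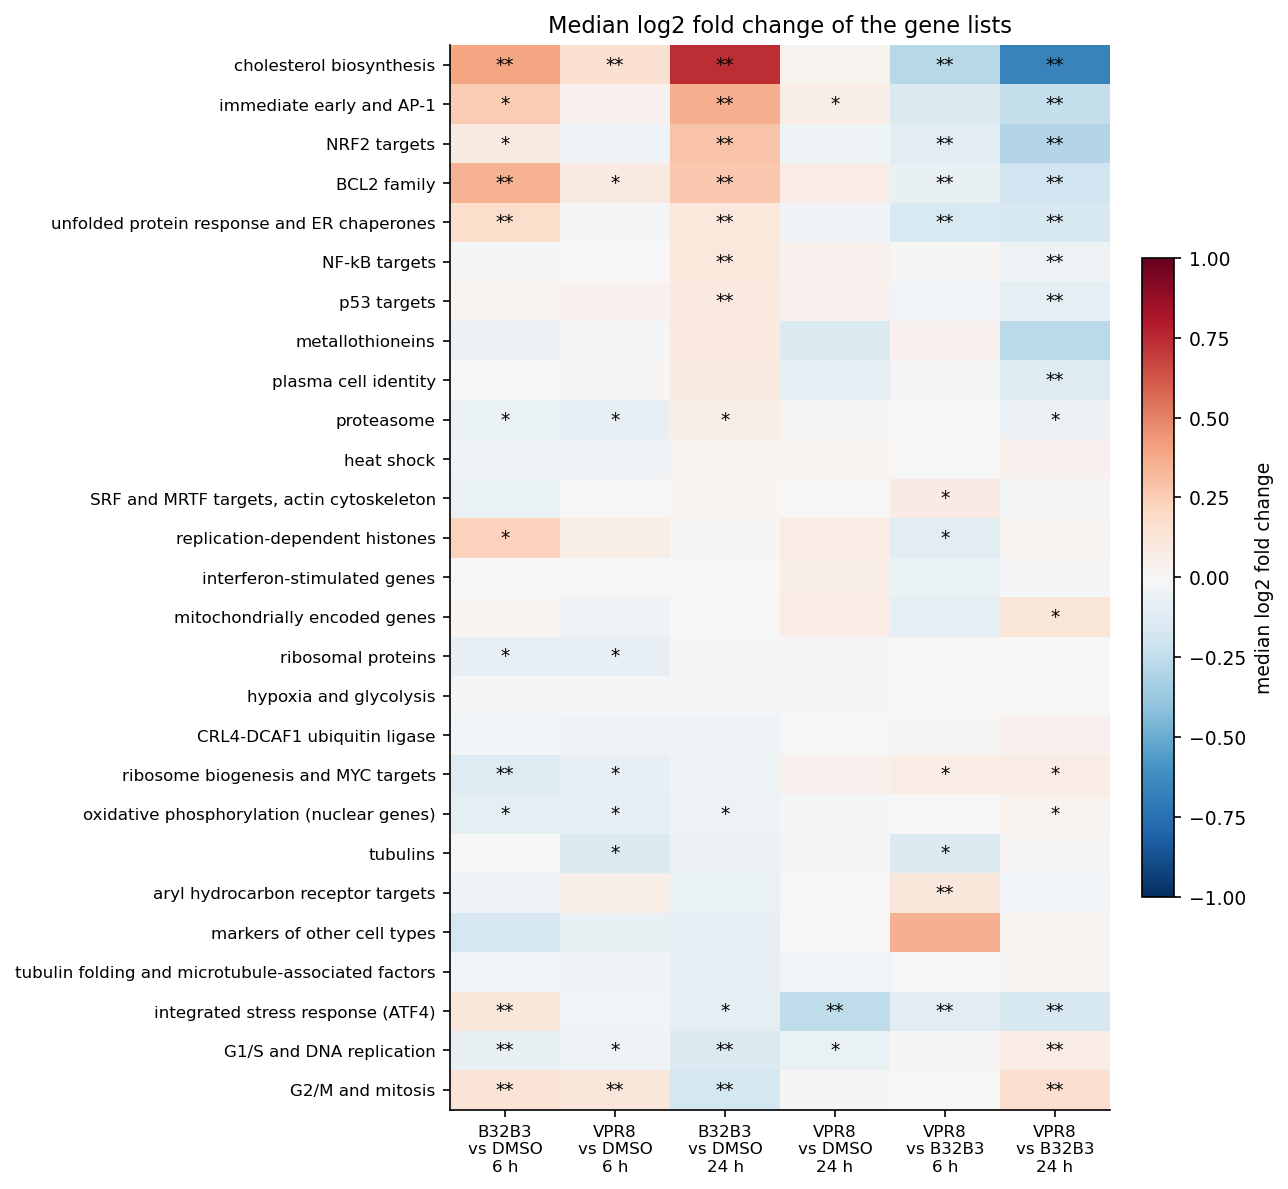
Median log2 change of each gene list (27 lists, rows) in each comparison (columns), as a colour scale. One asterisk marks a camera adjusted p below 0.05, and a pair marks lists that also passed with an estimated correlation, among them cholesterol biosynthesis with medians of 0.39 and 0.74 under B32B3 at 6 h and 24 h.

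DCAF1 was 38.5 ± 2.2 CPM in DMSO, 39.1 ± 4.96 under B32B3 and 38.0 ± 1.63 under VPR8 at 6 h, and 31.7 ± 1.94, 31.0 ± 1.29 and 32.8 ± 1.79 CPM at 24 h, with log2 changes from -0.03 to 0.05 that did not pass the test. None of the 10 CRL4-DCAF1 ligase genes was called in any of the 6 comparisons, over all genes or adjusted over the list alone (camera adjusted p from 0.392 to 0.965). Of the 10 tested tubulin genes, TUBA1A rose under B32B3 at 24 h from 29.03 ± 1.5 to 50.2 ± 1.6 CPM (log2 0.79 ± 0.08) and under VPR8 from 29.03 ± 1.5 to 38.0 ± 2.27 CPM (0.39 ± 0.09). The VPR8 call of TUBA1A was lost without DMSO replicate 1 (log2 0.35) or VPR8 replicate 2 (0.34). At 6 h TUBA1A was higher under B32B3 by 0.28 ± 0.07, and this call was lost without DMSO replicate 1 (0.22), DMSO replicate 2 (0.23) or B32B3 replicate 1 (0.27). The major beta-tubulin gene TUBB fell under B32B3 at 24 h from 2348 ± 19.5 to 2128 ± 89.7 CPM (-0.14 ± 0.04), a call lost without DMSO replicate 1 (-0.14) or B32B3 replicate 2 (-0.11). TUBA1A shares exon sequence with TUBA1C, and reads of near-identical tubulin genes may be split between them, so single tubulin values are uncertain.

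As a list, the tubulins had 0 of 10 members called under VPR8 at 6 h over all genes and 5 lower adjusted over the list alone (median -0.13; camera adjusted p = 0.000199, and 0.147 with an estimated correlation). Under B32B3 1 rose over all genes at 6 h and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.968). At 24 h 1 rose and 1 fell under B32B3 over all genes, and 2 rose and 2 fell adjusted over the list alone (adjusted p = 0.925). Under VPR8 1 rose over all genes, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.765). The 29 tubulin folding and microtubule-associated genes were not called as a list in any of the 6 comparisons (camera adjusted p from 0.38 to 0.963). Under B32B3 at 24 h 4 of them rose and 2 fell over all genes, and 4 rose and 5 fell adjusted over the list alone. They included CLIP1, a microtubule plus-end protein (0.30 ± 0.07), and the gamma-tubulin gene TUBG1, which overlaps RETREG3 (-0.25 ± 0.05).

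Further lists were not called against DMSO for either compound. The heat shock list (17 genes) had 2 members higher under B32B3 at 6 h over all genes, and 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.985); DNAJB1, an HSP40 co-chaperone gene that overlaps TECR, was 0.40 ± 0.06. The hypoxia and glycolysis list (27 genes) had 2 higher and 3 lower over all genes at 6 h of B32B3, and 5 and 5 adjusted over the list alone (adjusted p = 0.971). The interferon-stimulated list (16 genes) had 0 higher and 2 lower over all genes and also adjusted over the list alone in that comparison (adjusted p = 0.752). In the 6 aryl hydrocarbon receptor genes 0 rose and 1 fell (CYP1B1) over all genes, and 2 fell adjusted over the list alone (adjusted p = 0.128). In the SRF and actin list (23 genes) 0 rose and 2 fell over all genes at 6 h of B32B3, and 3 fell adjusted over the list alone, including the actin gene ACTG1 (-0.22 ± 0.04; adjusted p = 0.0677). At 24 h ACTG1 lay the other way, at 2693.4 to 2975.8 CPM in B32B3 libraries and 2277.1 to 2452.7 CPM in DMSO. Metallothioneins (3 tested genes) had 0 called over all genes and 1 higher adjusted over the list alone (adjusted p = 0.971), and the 13 mitochondrially encoded genes had 0 called over all genes and 0 adjusted over the list alone (adjusted p = 0.983). Only 3 of 29 markers of other cell types were abundant enough to test, and 0 were called over all genes or adjusted over the list alone (adjusted p = 0.649 for B32B3 at 6 h); EPCAM averaged 33.8 CPM, HBB 1.31 CPM and HBG2 1.07 CPM over all libraries.

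Compared directly at 6 h, VPR8 left sterol and stress genes below B32B3. HMOX1 was 54.2 ± 1.65 CPM under VPR8 and 103 ± 3.3 under B32B3 (log2 -0.92 ± 0.07), INSIG1 was 1623 ± 65.5 and 2818 ± 44.2 CPM (-0.80 ± 0.04), and HERPUD1 differed by -0.68 ± 0.06. In the cholesterol list 14 of 25 were lower under VPR8 over all genes and 17 adjusted over the list alone (median -0.28; camera adjusted p = 8.59e-31, and 0.000325 with an estimated correlation). Unfolded protein response genes had 6 of 25 lower over all genes and 10 adjusted over the list alone (adjusted p = 2.04e-12, and 0.00363 with an estimated correlation). Integrated stress response genes had 3 of 31 lower over all genes and 11 adjusted over the list alone (adjusted p = 1.34e-09, and 0.00183). NRF2 targets had 3 of 18 lower over all genes and 8 adjusted over the list alone (adjusted p = 3.48e-08, and 0.014 with an estimated correlation). BCL2 family genes had 3 of 14 lower over all genes and 5 adjusted over the list alone (adjusted p = 0.000676, and 0.0121). Among the 6 aryl hydrocarbon receptor targets CYP1B1 was higher under VPR8 over all genes (12.7 ± 1.36 against 7.03 ± 0.518 CPM; 0.85 ± 0.16), with 2 higher adjusted over the list alone (adjusted p = 0.00382, and 0.0267 with an estimated correlation). IRF4 was higher under VPR8 by 0.27 ± 0.05. The G2/M list, called for both compounds against DMSO, did not pass here (median difference 0.005, camera adjusted p = 0.993, 0 of 45 called over all genes and 0 adjusted over the list alone). CENPE differed by 0.01, with a 95% interval of -0.08 to 0.10 that rests only on the spread between these samples.

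edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 112 genes between the compounds at 6 h, 22 higher and 90 lower under VPR8. The count was 72 without VPR8 replicate 1 and 71 with the 6 h libraries fitted alone. Calls not kept with an estimated correlation were those of ribosome biogenesis genes (0 of 30 called over all genes and 0 adjusted over the list alone, adjusted p = 4.64e-05 by camera, and 0.107 with an estimated correlation) and of tubulins (1 of 10 lower over all genes, 3 adjusted over the list alone, adjusted p = 0.000222, and 0.107 with an estimated correlation). Histones were not kept either (0 of 23 over all genes, 0 adjusted over the list alone, adjusted p = 0.00666, and 0.211 with an estimated correlation). The SRF and actin list had 1 of 23 higher over all genes and 2 adjusted over the list alone (adjusted p = 0.00887, and 0.13 with an estimated correlation). The histone call was lost without B32B3 replicate 2 (adjusted p = 0.132), and the SRF call without B32B3 replicate 1 (0.0573), VPR8 replicate 1 (0.0611) or VPR8 replicate 2 (0.126), as adjusted p-values.

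At 24 h the compounds differed more. MSMO1 was at 65.6 ± 2.2 CPM under VPR8, 66.3 ± 4.54 in DMSO and 130 ± 8.64 under B32B3, with a log2 difference of -0.98 ± 0.06 between the compounds. HMGCS1 differed by -1.54 ± 0.04 and CYP51A1, the lanosterol demethylase, by -0.93 ± 0.06. In the cholesterol list 20 of 25 were lower under VPR8 over all genes and 23 adjusted over the list alone (median -0.67; camera adjusted p = 1.04e-49, and 1.35e-05 with an estimated correlation). G2/M genes were higher under VPR8, 17 of 45 over all genes and 29 adjusted over the list alone, with UBE2C at 89.3 ± 3.85 against 69.2 ± 3.39 CPM (0.37 ± 0.06) and CDC20, the activator of the anaphase-promoting complex, at 0.32 ± 0.06 (median 0.17; adjusted p = 4.28e-21, and 1.82e-06 with an estimated correlation). NRF2 targets were lower, 11 of 18 over all genes and 12 adjusted over the list alone, with SQSTM1 at -1.21 ± 0.04 and FTL at -0.35 ± 0.04 (adjusted p = 5.34e-17, and 0.000786 with an estimated correlation). CCL3 differed by -2.04 ± 0.10 and EGR1 by -1.54 ± 0.21. The selenoprotein gene SELENOW was higher under VPR8, at 81.0 ± 1.52 against 49.0 ± 2.24 CPM (0.72 ± 0.07).

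Further lists were lower under VPR8 than under B32B3 at 24 h. Integrated stress response genes had 10 of 31 lower over all genes and 12 adjusted over the list alone (camera adjusted p = 1.2e-10, and 0.000786 with an estimated correlation). Unfolded protein response genes had 6 of 25 lower and 9 adjusted over the list alone (adjusted p = 2.72e-11, and 0.00301). Immediate early genes had 6 of 19 and 6 adjusted over the list alone (adjusted p = 3.99e-07, and 0.00252), and BCL2 family genes 3 of 14 and 5 adjusted over the list alone (adjusted p = 0.000222, and 0.00414). NF-κB targets had 4 of 17 and 4 adjusted over the list alone (adjusted p = 0.000529, and 0.0188). Plasma cell identity genes had 4 of 20 lower, 6 adjusted over the list alone, with POU2AF1 at -0.27 ± 0.05 (adjusted p = 0.000328, and 0.0254). The p53 targets had 4 of 22 lower and 4 adjusted over the list alone (adjusted p = 0.00262, and 0.0223). The second p of each pair is the one with an estimated correlation. G1/S genes had 2 of 41 higher over all genes, and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00328, and 0.0223 with an estimated correlation). TUBA1A was lower under VPR8 by -0.40 ± 0.08, and BCL2L11, a pro-apoptotic BH3-only gene, differed by -0.08 with a 95% interval of -0.25 to 0.09. BCL2L11 overlaps MIR4435-2HG.

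edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 464 genes between the compounds at 24 h, 144 higher and 320 lower under VPR8, and 309 without B32B3 replicate 2. The number higher was 82 without B32B3 replicate 2, 95 without B32B3 replicate 3, 90 without VPR8 replicate 1 and 83 without VPR8 replicate 2. Calls not kept with an estimated correlation were the proteasome (0 of 33 called over all genes, 0 adjusted over the list alone, adjusted p = 0.00188 by camera, and 0.363 with an estimated correlation) and ribosome biogenesis (1 of 30 higher over all genes, 1 adjusted over the list alone, adjusted p = 0.00302, and 0.219 with an estimated correlation). Others were oxidative phosphorylation (0 of 67 over all genes, 0 adjusted over the list alone, adjusted p = 0.0123, and 0.613 with an estimated correlation) and mitochondrially encoded genes (0 of 13 over all genes, 0 adjusted over the list alone, adjusted p = 0.0251, and 0.549 with an estimated correlation). The mitochondrially encoded list was lost without B32B3 replicate 1 (0.287), VPR8 replicate 1 (0.0922) or VPR8 replicate 2 (0.0514), as adjusted p-values. Oxidative phosphorylation was lost without B32B3 replicate 2 (0.172) or VPR8 replicate 2 (0.124), and with the lincRNA share as a covariate (0.266). Ribosome biogenesis was lost without VPR8 replicate 1 (0.053).

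**Figure D4:**
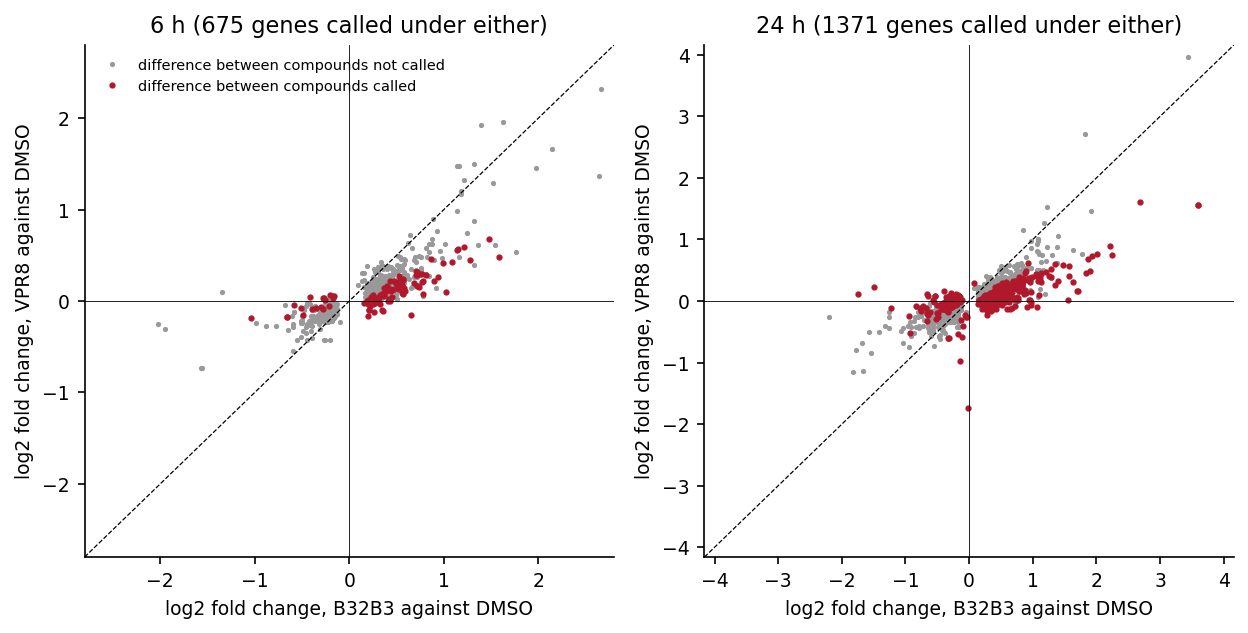
Log2 change under VPR8 (vertical) against that under B32B3 (horizontal) of the genes called under either, 675 at 6 h and 1371 at 24 h, both against the same 3 DMSO libraries of that time. The correlations across all 13724 tested genes were 0.622 and 0.592, and unchanged groups simulated against shared controls gave 0.498 and 0.505.

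INSIG1, HMGCS1 and MSMO1 were called higher for both at 6 h, and CCL3 and SQSTM1 at 24 h. Higher calls shared by both compounds numbered 33 at 6 h (368 and 42 called; independent lists would share 1.13) and 66 at 24 h (747 and 72 called; 3.92). Lower calls shared numbered 5 at 6 h (294 and 9; 0.193) and 44 at 24 h (602 and 61; 2.68). Across 13724 genes, which are not independent replicates, the log2 changes of the compounds had a correlation of 0.622 at 6 h, against a simulated mean of 0.498 (0.462 to 0.525 over 100 simulations). At 24 h it was 0.592 against 0.505 (0.475 to 0.527). The simulations drew each gene independently, so they hold no difference common to a whole library, such as that in lincRNA share. At 6 h the observed correlation was 0.524 without VPR8 replicate 3, a library with a high lincRNA share. No simulation left that library out, so how much it adds to the excess cannot be told. The covariance was 0.0369 at 6 h against a simulated 0.02, a difference of 0.0169, and 0.0336 at 24 h against 0.0172, a difference of 0.0165. The simulations used 1 spread per gene for both times, although DMSO replicates varied more at 6 h. The simulated covariance may thus be too low at 6 h and too high at 24 h, and the differences cannot be compared between times. With 3 DMSO libraries per time the controls cannot be split into parts of at least 2, so part of the excess in overlap may come from the shared controls.

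By the test of the difference itself, 102 of the 662 genes called for B32B3 at 6 h differed between the compounds, and 15 of the 51 called for VPR8. At 24 h these were 376 of 1349 and 46 of 133. In all 102 at 6 h and in 374 of the 376 at 24 h, VPR8 lay on the side of B32B3 toward 0. Genes chosen for a change under B32B3 lean this way. No gene was called in opposite directions for the compounds at either time. All 51 and 133 genes called for VPR8 had the sign of their B32B3 change, which shared controls favour. Of the genes called for VPR8, 13 at 6 h and 23 at 24 h were not called for B32B3. For 10 of those 23 the difference was called and the VPR8 change was the farther from 0, and 4 of the 10 belong to the integrated stress response list: SESN2 (-0.58 under VPR8 and -0.11 under B32B3), STC2 (-0.40 and -0.09), DDIT3 (-0.27 and -0.05) and ATF4 (-0.23 and -0.06). Others were the transaminase gene GPT2 (-0.31 and -0.12), MAP1B, a microtubule-associated protein gene (-0.53 and -0.17), ITGB7 (-0.27 and -0.03), GHR (-1.73 and -0.02) and OLMALINC (-0.97 and -0.14), and all of these were named after their values were seen.

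The effect of each compound also differed between times. For B32B3, G2/M genes went from higher at 6 h to lower at 24 h, and the difference (24 h effect minus 6 h effect) was negative in 18 of 45 over all genes and 33 adjusted over the list alone, with TOP2A at -0.30 ± 0.06 and UBE2C at -0.38 ± 0.09 (median -0.31; camera adjusted p = 1.75e-22, and 1.17e-06 with an estimated correlation). Integrated stress response genes had 3 positive and 10 negative differences of 31 over all genes, and 4 and 15 adjusted over the list alone (adjusted p = 3.14e-06, and 0.0115 with an estimated correlation). NRF2 targets had 8 of 18 positive over all genes, and 8 positive and 1 negative adjusted over the list alone, with SQSTM1 at 1.16 ± 0.06 (adjusted p = 3.14e-06, and 0.0342 with an estimated correlation). NF-κB targets had 5 of 17 positive over all genes, and 7 positive and 1 negative adjusted over the list alone, with CCL3 at 2.83 ± 0.17 (adjusted p = 0.000242, and 0.0312 with an estimated correlation). Immediate early genes had 4 of 19 positive over all genes and 6 adjusted over the list alone, with EGR1 at 1.51 ± 0.25 (adjusted p = 0.000736, and 0.0342 with an estimated correlation). Within the cholesterol list 8 differences were positive and 4 negative over all genes, and 11 and 4 adjusted over the list alone: HMGCS1 stood at 0.56 ± 0.06, whereas INSIG1 stood at -0.41 ± 0.06 (adjusted p = 0.00154, and 0.198 with an estimated correlation). HMGCS1 was 846.6 to 852.2 CPM in B32B3 libraries at 6 h and 811.7 to 855.5 CPM at 24 h. In DMSO libraries HMGCS1 was 365.2 to 412.6 and 254.2 to 259.1 CPM at these times, so its difference came from the control. INSIG1 was 2784.8 to 2868.0 and 3323.0 to 3486.8 CPM under B32B3, so its level did not fall there. SQSTM1 was 2236.0 to 2485.9 and 1465.4 to 1493.3 CPM under B32B3, and 1266.9 to 1432.3 and 381.9 to 390.8 CPM in DMSO. EGR1 was 17.7 to 19.9 and 6.6 to 9.0 CPM under B32B3, and 17.7 to 19.1 and 2.1 to 3.2 CPM in DMSO. SQSTM1 and EGR1 fell with time under B32B3, and their positive differences came from a larger fall in DMSO. CCL3 was 41.8 to 45.7 and 44.8 to 54.3 CPM under B32B3, and 23.2 to 27.2 and 3.9 to 4.7 CPM in DMSO. The proteasome (4 of 33 positive over all genes, 6 adjusted over the list alone, adjusted p = 0.208 with an estimated correlation) was called by camera and not kept. So were ribosome biogenesis (5 of 30, 9 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation) and ribosomal proteins (1 of 79, 1 adjusted over the list alone, adjusted p = 0.771 with an estimated correlation). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 498 genes, 290 with a positive and 208 with a negative difference.

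For VPR8, 7 of 25 cholesterol genes were called higher at 6 h and 0 at 24 h. The difference between times was negative for INSIG1 (-0.78 ± 0.06), MSMO1 (-0.46 ± 0.10) and HMGCS1 (-0.41 ± 0.06). INSIG1 in DMSO libraries was 975.9 to 1033.7 CPM at 6 h and 1588.9 to 1640.2 CPM at 24 h, so much of its difference lay in the control. Of 25 cholesterol genes 3 differences were negative over all genes and 6 adjusted over the list alone (camera adjusted p = 0.000251, and 0.211 with an estimated correlation). Integrated stress response genes had 5 of 31 negative over all genes and 14 adjusted over the list alone, with SESN2 at -0.66 ± 0.13 (median -0.23; adjusted p = 1.18e-10, and 0.00182 with an estimated correlation). G2/M genes had 0 of 45 over all genes and 7 negative adjusted over the list alone (median -0.09; adjusted p = 5.44e-05, and 0.00183 with an estimated correlation). CCL3 differed by 1.36 ± 0.20 and SQSTM1 by 0.51 ± 0.06, and both genes fell with time in DMSO. Other camera calls had adjusted p-values with an estimated correlation of 0.211 for ribosome biogenesis, 0.342 for tubulins, 0.483 for NRF2 targets, 0.537 for the proteasome and 0.627 each for ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes. Over all genes these lists had 0 members called, except 1 NRF2 target, and adjusted over the list alone 2 ribosome biogenesis, 2 tubulin, 4 NRF2 and 1 ribosomal protein gene were positive. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 39 genes, 21 positive and 18 negative (53.8% positive). This balance did not hold. It was 80.6% with DESeq2, 48.3% with the lincRNA share as a covariate and 48.8% with no filter on low counts. It was 47.8%, 48.4% and 38.5% without the 6 h VPR8 replicates 1, 2 and 3, and 45.5% and 42.9% without the 24 h DMSO replicates 1 and 2. Without the 24 h VPR8 replicates 1 and 2 it was 35.3% and 43.3%. The count was 72 with DESeq2, 23 without the 6 h VPR8 replicate 1, and 22, 21 and 22 without the 24 h DMSO replicates 1, 2 and 3. It was 17 and 19 without the 24 h VPR8 replicates 1 and 3. Without the 6 h VPR8 replicate 3 the number of called lists went from 10 to 6.

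In DMSO alone, 24 h and 6 h libraries differed in many genes. The immediate early list fell, with 14 of 19 genes lower over all genes and 14 adjusted over the list alone, such as EGR1 (18.4 ± 0.679 to 2.58 ± 0.549 CPM; -2.82 ± 0.18; list median -0.48, camera adjusted p = 4.61e-06, and 0.0227 with an estimated correlation). HMOX1 fell from 50.5 ± 4.15 to 6.75 ± 0.492 CPM (-2.90 ± 0.12). SQSTM1 and CCL3 also fell (log2 -1.81 ± 0.04 and -2.62 ± 0.15). DDIT4, a stress-induced inhibitor of mTORC1, rose from 11.5 ± 3 to 72.7 ± 2.26 CPM (2.67 ± 0.10), and VEGFA, the vascular growth factor, rose from 19.04 ± 0.483 to 62.6 ± 2.95 CPM (1.72 ± 0.09). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6831 genes, 3338 higher and 3493 lower at 24 h, and 2062 with the lincRNA share as a covariate. The 24 h and the 6 h libraries carry separate blocks of library names, so time and library set cannot be told apart in this comparison. The 10 other lists called by camera were not kept with an estimated correlation, which gave adjusted p-values of 0.0503 for the unfolded protein response and 0.0627 each for ribosome biogenesis, NF-κB and SRF lists. The values were 0.145 for NRF2 targets, 0.169 for metallothioneins, 0.17 for the integrated stress response, 0.394 each for ribosomal proteins and the proteasome and 0.523 for oxidative phosphorylation. Members lower at 24 h over all genes, and adjusted over the list alone, were 69 and 70 of 79 ribosomal protein genes, 22 and 22 of 30 ribosome biogenesis genes and 18 and 19 of 25 unfolded protein response genes. They were 13 and 13 of 23 SRF targets, 9 and 9 of 18 NRF2 targets, 9 and 9 of 17 NF-κB targets, 19 and 20 of 33 proteasome genes, 28 and 28 of 67 oxidative phosphorylation genes and 3 and 3 of 3 metallothioneins. In the integrated stress response list 16 rose and 8 fell over all genes and also adjusted over the list alone.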

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

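The tests on overlapping genes and on the change of DMSO cultures with time were chosen only after those results were seen. The tests on lincRNA genes were written before their values were computed, but the lincRNA covariate was itself chosen after the data were seen. Results below were flagged because a compound's effect at 24 h differed from its effect at 6 h by the test of the difference, edgeR's quasi-likelihood test for genes and camera, also with an estimated correlation, for lists. Values are log2 differences, 24 h effect minus 6 h effect. Each effect is relative to DMSO, which itself differed between times, so a difference can arise without a change in level under the compound.

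For B32B3 the differences of 5 lists were flagged, with medians of -0.31 for G2/M and mitosis, -0.23 for the integrated stress response, 0.145 for NRF2 targets, 0.22 for NF-κB targets and 0.27 for immediate early genes. Of the named genes reported here 65 were flagged, 36 positive and 29 negative. Positive differences were CCL3-AS1 2.85, CCL3 2.83, CCL4 2.12, SPSB1 1.97, EGR1 1.51, PTP4A3 1.45, PARP9 1.42, FAM43A 1.38, SQSTM1 1.16, MRNIP 1.16, ICAM1 1.01, CYP1B1 0.95, ZMAT3 0.84, HMOX1 0.80, CYP51A1 0.60, FTH1 0.57, ENSG00000261604 0.56, HMGCS1 0.56, PPP1R15A 0.55, FTL 0.52, TUBA1A 0.51, ACTG1 0.48, BTG2 0.48, TPM4 0.47, IER2 0.47, TNFAIP3 0.39, TRIAP1 0.37, CCND2 0.33, NOP58 0.31, NFKBIA 0.30, PSMD1 0.30, POMP 0.29, MRTO4 0.27, PSMB7 0.26, SLIRP 0.24 and JCHAIN 0.23. Negative differences were ENSG00000225889 -1.09, CHAC1 -0.81, KIAA1549L -0.80, IL6R -0.78, SESN2 -0.54, PSAT1 -0.50, NUF2 -0.48, CDT1 -0.44, PRC1 -0.42, KIF20A -0.42, MZB1 -0.42, INSIG1 -0.41, PHGDH -0.39, ASPM -0.38, UBE2C -0.38, PMAIP1 -0.38, CENPE -0.36, ATF4 -0.34, BBC3 -0.34, AURKA -0.33, NUSAP1 -0.33, PLK1 -0.33, MSMO1 -0.31, MAF -0.31, TOP2A -0.30, STC2 -0.29, BCL2 -0.29, CKAP5 -0.24 and TYMS -0.23.

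For VPR8 the differences of 2 lists were flagged, with medians of -0.23 for the integrated stress response and -0.085 for G2/M and mitosis. Of the named genes reported here 14 were flagged, 5 positive and 9 negative. Positive differences were CCL3-AS1 1.41, CCL3 1.36, MRNIP 0.53, SQSTM1 0.51 and NFKBIA 0.31. Negative differences were INSIG1 -0.78, SESN2 -0.66, IL6R -0.53, MSMO1 -0.46, PHGDH -0.45, PSAT1 -0.42, HMGCS1 -0.41, ENSG00000261604 -0.40 and ATF4 -0.26.

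Of 387 tested lincRNA genes, 8 were called higher and 3 lower under B32B3 at 6 h. With each library's lincRNA share as a covariate the median rise of the 8 went from 1.21 to 0.44, a ratio of 0.361, and 3 stayed called; the covariate contains these genes' own reads, so a library difference in RNA quality remains possible and is not shown. The 8 genes had a median of 23 counts per library at 6 h, and their means ranged from 10.2 (MIR34AHG) to 2898.2 (NEAT1). All had already passed the filter on low counts, so this median says little on whether reads were too few. The lowest B32B3 library reached 0.565 of the mean rise, as a response in every culture would give. These genes were chosen for being higher in the same libraries, so this value cannot decide. The medians were 1.277, 0.587 and 1.255 in B32B3 replicates 1, 2 and 3, higher in replicates 1 and 3, which had the larger lincRNA share. VPR8 replicate 3 stood at 1.05 against 0.21 and 0.37 in the other VPR8 libraries. The 8 genes did not move alike with the covariate. INSIG1-DT went from 0.92 to 1.03 and ENSG00000258908 from 0.33 to 0.31. The others fell by more, MIR29B2CHG most, from 1.24 to 0.16. Replicate RNA integrity values, or a repeat from new cultures, would separate the explanations, and for the 8 as a set neither may be judged from these counts.

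Genes that overlap on the genome differed less in log2 change than neighbours without overlap. Where the gene with more counts was called, the median absolute difference in log2 change was 0.229 between overlapping genes (31% of 3280 combinations of pair and comparison within 0.1) and 0.416 between neighbours without overlap (11.6% of 9067 such combinations within 0.1). The partner was called in the same direction in 20.4% of 773 overlapping and 4% of 2254 neighbouring combinations of the 4 comparisons with DMSO. The median of 0.416 argues against a general tendency of neighbours to change together without shared reads. These neighbours may lie at any distance, so that median cannot exclude shared regulation of overlapping genes. The median of 0.229 leaves double counting of reads open. CCL3 with CCL3-AS1 and SQSTM1 with MRNIP had correlations of 0.998 and 0.999 over the 18 libraries. No other biological explanation was tested, and strand-specific counting could settle the question.

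Genes that rose with time in DMSO tended to be lower under B32B3 at 24 h, and the reverse: 424 genes fell with time and were higher under B32B3, against 99 that fell in both. With the DMSO 24 h libraries split between the 2 comparisons, the 200 genes that rose most had a median B32B3 effect of -0.173 (-0.274 to -0.084 over 6 splits), and those that fell most 0.183, which leaves a slower change of treated cultures with time open. The correlation across genes was -0.351 with all DMSO 24 h libraries in both and -0.212 with split controls. Chance values of the shared libraries may account for part of it, and the second value argues against chance values of single libraries being all of it. A deviation common to all DMSO 24 h libraries would enter both comparisons even when they are split, so the split cannot address it. Of the 424, 15.6% were also called higher at 6 h, against 28.8% of the other genes higher under B32B3 at 24 h. With so few calls at 6 h in either set, a missing call is not a missing response, and a response present from the start stays open. VPR8 at 24 h leant the same way with split controls. Its mean correlation was -0.126, and the 200 genes that rose and fell most had mean medians of -0.104 and 0.09. A slower change therefore stays open for VPR8 too. A sampling of cell number and medium at each time could test the slower change.

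As a check of the groups, libraries were also split in other ways. With 10 splits per comparison the splits are too few for a share under 0.05. Only 1 of 10 splits, the true grouping itself, called that many genes for B32B3 against DMSO at 6 h (662, highest other 5), VPR8 at 6 h (51, highest other 5), B32B3 at 24 h (1349, highest other 0), VPR8 at 24 h (133, highest other 0), VPR8 against B32B3 at 24 h (464, highest other 0) and DMSO with time (6831, highest other 1). For VPR8 against B32B3 at 6 h 2 of 10 splits called at least 112 genes, the other calling 231. That split puts B32B3 replicate 2 with VPR8 replicates 1 and 2, which follows the lincRNA share, so it points to a structure of the samples. For the differences between times, 5 of 100 splits drawn from 200 called at least as many genes as the true grouping, for B32B3 (498, highest other 1463) and for VPR8 (39, highest other 157). The 4 others of each kept the 24 h labels and exchanged 2 or 3 libraries at 6 h, so they still contain treatment effects, and chance is not excluded by this count.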

How the results depend on the processing

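Direction was checked for named genes in the comparisons within 6 h or 24 h, and for lists called in the main test. None of these passed in the opposite direction under the alternatives checked. The filters on low counts and the fit without overlapping genes were not checked for direction. The share of VPR8 calls that were higher turned from 82.4% to 25.6% with DESeq2 and 41.9% without DMSO replicate 1 at 6 h, and from 54.1% to 42.3% without VPR8 replicate 2 at 24 h. For the VPR8 difference between times 53.8% were positive, 80.6% with DESeq2 and as few as 35.3% without the 24 h VPR8 replicate 1. The lincRNA share and the fit without overlapping genes were chosen after the data were seen. The counts of called genes below moved by more than 1.5 times, and the cause was not tested. With a log2 change of at least 1, which by construction drops smaller changes, 34 genes were called for B32B3 at 6 h, 7 for VPR8 at 6 h, 82 for B32B3 at 24 h and 11 for VPR8 at 24 h, 2 and 28 between the compounds at 6 h and 24 h, 36 and 3 for the differences between times of B32B3 and VPR8, and 1148 for DMSO with time. DESeq2 called 125 genes for VPR8 at 6 h and 72 for its difference between times, and limma-voom 33 for VPR8 at 6 h. With 1 time point alone the counts fell to 373 for B32B3 at 6 h, 21 for VPR8 at 6 h and 71 between the compounds at 6 h. For VPR8 at 24 h the count rose from 133 to 254, although fewer samples were fitted. It also rose for B32B3 at 24 h, from 1349 to 1789, by less than 1.5 times. The main fit shared its spread over both times, and replicates varied more at 6 h than at 24 h. Counts at 6 h and 24 h from the main fit are therefore not directly comparable. With the lincRNA share as a covariate the counts were 279 for B32B3 at 6 h, 219 for VPR8 at 24 h and 2062 for DMSO with time. Of the 662 genes of B32B3 at 6 h, 216 were called in both fits.

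With 1 library left out, counts ranged from 353 to 854 for B32B3 at 6 h, 26 to 117 for VPR8 at 6 h, 69 to 130 for VPR8 at 24 h, 72 to 94 and 309 to 342 between the compounds at 6 h and 24 h, and 17 to 56 for VPR8 between times. Some counts fell and others rose although fewer samples were left. VPR8 at 6 h went from 51 to 117 without DMSO replicate 1, and B32B3 at 6 h from 662 to 854 without B32B3 replicate 2. The cause was not tested. Lists called ranged from 1 to 4 for VPR8 at 24 h and 6 to 11 for VPR8 between times. The correlation between the compounds ranged from 0.524 to 0.702 at 6 h and from 0.535 to 0.645 at 24 h; among genes called in either comparison it was 0.846 and 0.809, genes selected for large changes. With an estimated correlation, lists called were 7 for B32B3 and 2 for VPR8 at 6 h, 1 for VPR8 at 24 h, 6 between the compounds at 6 h, 5 and 2 for the differences of B32B3 and VPR8, and 1 for DMSO with time. fry called 4 for the VPR8 difference and 23 for DMSO with time, and the lincRNA covariate left 6 for the VPR8 difference.

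Replicate numbers did not pair the samples: same-numbered samples correlated from -0.103 to 0.114 over 18 pairs, 8 of them best with their own number. With the replicate block 135 genes were called for VPR8 at 6 h and 95 for its difference between times, and no other count moved by more than 1.5 times. The block also ended 2 list calls, immediate early genes for B32B3 at 6 h (adjusted p = 0.0818) and the BCL2 family for VPR8 at 6 h (adjusted p = 0.0792). Of 292 called results on named genes, those no longer called numbered 0 with RLE scaling, 22 with DESeq2, 23 with limma-voom, 37 with 1 time point alone, 45 with the lincRNA covariate and 1 with the block, and 28 had no adjusted p from DESeq2. Over all single left-out libraries 358 calls were lost, with a result counted once for each library whose removal lost it. Depth limits low genes: 3 counts stand for 0.371 to 0.478 CPM. With these depths, 3 libraries per group and this spread together, 28% of planted 1.25-fold changes were recovered for B32B3 at 24 h among 13724 genes.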

Other observations

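The test of lysosomal genes was chosen only after the result was seen. SQSTM1, NPC2, CD63 and other genes linked to lysosomes stood among the increases under B32B3 at 24 h, so a list of lysosomal genes was tested without the 7 members that prompted it. Of the remaining 45, 19 rose and 1 fell, with a median log2 change of 0.26 (camera p = 4.92e-05 with an estimated correlation). They include the proteases CTSD (0.62 ± 0.06) and CTSB (0.63 ± 0.09), the sphingolipid activator precursor PSAP (0.48 ± 0.04), the membrane protein LAMP1 (0.26 ± 0.05) and the sulfatase SGSH (1.05 ± 0.18). Under VPR8 at 24 h 2 rose, CTSB and PSAP (median 0.09, camera p = 0.00525 with an estimated correlation), and VPR8 lay below B32B3 in 11 of 45 (median -0.15, p = 0.000164).

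At 6 h 3 of the 45 rose under B32B3 (median 0.06, p = 0.042) and 0 were called under VPR8 (median 0.00, p = 0.906; camera with an estimated correlation, single genes by edgeR). Together with the cholesterol genes, this may suggest that B32B3 disturbs lysosomal or sterol transport by 24 h (camera p = 4.92e-05 for the list with an estimated correlation, 1 list tested and not adjusted), a hypothesis from these same samples that new samples would have to test, for example by filipin staining of cholesterol and LysoTracker imaging.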
